A study of Mus musculus with 32 samples.

How the data were processed

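The data were 32 arrays of 2-colour cDNA type, 12 from eye, 12 from brain and 8 from heart. Each compared RNA of a sighted C3H sample with a pool of RNA from 6 control males, and the brain and heart pools came from the same mice while the eye pool came from other mice. Total RNA was reverse transcribed and labelled indirectly with Cy3 or Cy5, per the labels' protocols. The dye of the sighted RNA came from the labels, except that the label of brain array 3 gives Cy5 for both channels and was read as Cy5 for the sighted RNA. The label of brain array 5 names its source only as sighted.

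The deposited values are log2 ratios of Cy5 over Cy3 within an array. The scanner, background correction and normalization are not given in the sources used here. Array medians lay between -0.061 and 0.535 in eye, between 0.002 and 0.1 in brain and between 0.034 and 0.217 in heart, so the arrays were not all centred, and whether and how they were scaled stays unknown. The direction of the ratio was inferred from the rod genes on the eye arrays and is called likely. The deposited values of 6744 genes were averaged over both dye orientations. In this mean the difference between sighted and control RNA cancels and the dye effect of each gene remains. This dye component had a Spearman correlation of 0.431 between eye and brain, 0.394 between eye and heart and 0.578 between brain and heart. These correlations are across genes, which are not independent replicates, and they are the basis for using 1 direction in all organs.

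Most arrays repeat 1 value above 15 at the top of their range, 16.61 on all eye arrays. These 4170 values were treated as missing, a choice made after seeing the data. In all, 5.88% of values were missing as deposited. The 32 columns were all mapped to samples.

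Of 20794 probes, 12771 carried 1 gene symbol, 0 carried several and 8023 carried none. The named probes gave 9030 genes, of which 2754 had more than 1 probe, and probes of a gene were averaged. Probes without a name stayed in the tests under their number. Symbols were compared with a RefSeq table of the mouse assembly GRCm38.p6, which changed 0 of them and was used for names and gene order only.

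Ratios of arrays with sighted RNA in Cy3 were turned in sign. Consecutive arrays of opposite dye were averaged to a replicate, which needed both arrays, and a gene could miss 1 replicate. This pairing is a reading of the array numbers. After removal of the mean of each dye orientation, arrays of the same pair had a mean correlation of 0.146 in eye, 0.0162 in brain and -0.0359 in heart.

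Each organ was tested with limma 3.58.1 in R 4.3.3, the mean against 0, two-sided, with moderated variances and Benjamini-Hochberg adjustment at 0.05. Differences between organs were tested in 1 limma fit of all organs with a shared spread, over genes measured in all of them. A fit with each organ's own moderated spread was added after seeing the data, because simulated data showed false calls with the shared spread. Brain and heart shared their control mice, which the difference test does not model.

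The 27 gene lists were written before the data were examined, and covered rod, cone, bipolar, amacrine and horizontal, ganglion, Mueller and astroglia, pigment epithelium, lens, cornea, muscle, fat, blood, immune, heart, matrix, synapse, myelin, choroid plexus, cortex and striatum, hormone, clock, immediate early, heat shock, metabolic and ribosomal genes. Lists with at least 4 genes measured in every replicate were tested with camera on those genes, at a preset correlation of 0.01, and with an estimated correlation. Fry, a limma set test that does not compare a list with the other genes, was run beside it. All were adjusted over the lists of an organ. Camera with an estimated correlation passed no list, also where the estimate lay below 0.01. In that setting it takes its degrees of freedom from the few replicates and not from the many genes. It therefore has little power here. A call lost there is neither by itself a sign of correlation between genes nor evidence against a list. Genes near Pde6b were tested with Fisher's exact test.

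The genes to name were fixed by a rule before the data were examined. It took, per organ, the 10 largest changes each way among called genes with 1 sign in every replicate, or up to 5 genes by smallest p where fewer than 5 passed. It added up to 4 called members per list and the 5 named genes with the smallest p for each organ difference. For lists without a called member it took 2 members by smallest p. In brain and heart these are given only for lists past camera, and the other lists by their test, which is less than the rule asked.

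Alternatives were every array on its own, with and without the pair as a random block, centred or scaled arrays, other handling of missing values, single probes, robust moderation, a single dye orientation, a filter on the 20% of genes with most spread between arrays, and each replicate left out. Every array on its own may count colour flips of the same animal as separate samples. Scaling divided by the median absolute value, since the scaling planned first failed on missing values. For single probes, the probe with the smallest p stood for a gene, which favours keeping a call.

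The tests were tested on simulated data with the spread of these samples, in which 200 genes changed. The eye test recovered 64.2% of genes changed by a log2 of 0.5 and 86.6% of those changed by 1. The brain test recovered 55.2% and 82.1%. The heart test recovered 0% and 22.4%. The simulation took sample SDs as true, which widens the differences in spread between genes. With 200 changed genes the adjustment asks less of each gene than where few genes change. The shares recovered can therefore be too high for brain and heart, where limma called 1 and 0 genes. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables.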

Results

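The data came from 32 cDNA arrays with 2 colours that set organ RNA of sighted C3H mice against RNA of control C3H mice, which carry inherited retinal degeneration. Each array held RNA of 1 sighted sample and a pool of RNA from 6 control males of the same organ. Eye and brain had 12 arrays each and heart had 8. The sighted RNA carried Cy5 on arrays with an odd number and Cy3 on arrays with an even number, apart from a conflict in the label of brain array 3. An array held 20794 probes. The share of missing values lay between 1.62 and 5.10% on the eye arrays and between 1.01 and 5.05% on the brain arrays. On the heart arrays it lay between 5.96 and 61.58%. The number of arrays limits the precision.

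A replicate is the mean of 2 arrays with consecutive numbers and opposite dyes, which gave 6 replicates for eye, 6 for brain and 4 for heart. The design text of the series says that the arrays include colour flips of 6 animals. The labels do not say which arrays share an animal, so the p-values measure the spread between these samples, which may be partly technical. The control RNA of an organ is 1 pooled sample, and every test leaves out the spread between control animals. Values are log2 ratios of sighted over control RNA. Their direction is likely, not stated: on the eye arrays the rod gene list had a median between 3.37 and 3.68 with sighted RNA in Cy5, and between -3.26 and -2.51 with sighted RNA in Cy3. The rod list therefore served to orient the ratios and is no independent evidence of their direction.

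The sighted and control mice are expected to differ at Pde6b, the rod phosphodiesterase gene that is mutated in C3H mice with retinal degeneration. No probe was named Pde6b here, so the target gene itself has no value.

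The first comparison asked which genes differed in the eye between sighted and control mice. Of 17 rod photoreceptor genes measured, 16 rose in sighted eyes, and the list passed camera. With an estimated correlation camera gave it an adjusted p = 0.175, but in that setting it has little power and passed no list in any organ. Guca1b, which encodes a guanylate cyclase activator, was higher by a log2 ratio of 6.45 ± 0.20 (SD, n = 6), or 87.2-fold. Sag, the rod arrestin gene, had 5.35 ± 0.14 (SD, n = 6), or 40.8-fold. Of the cornea and surface epithelium list 10 of 13 genes fell, of skeletal muscle 13 of 16, of fat 6 of 10, of immune cells 14 of 18 and of blood 3 of 3, while the muscle gene Pvalb rose. The first 4 of these lists passed camera, with an adjusted p = 0.218, 0.398, 0.227 and 0.243 with an estimated correlation. Of 15874 genes tested with limma, 4259 passed an adjusted p of 0.05 after Benjamini-Hochberg adjustment, 2520 higher and 1739 lower. The counts of called genes in the eye lists are to be read beside this share. The median over all genes was 0.03.

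Adjusted over the list alone, 16 rod genes rose as well. Esrrb, an orphan nuclear receptor gene, rose by 5.44 ± 0.46 (SD, n = 6). Cngb1, a subunit gene of the rod cyclic nucleotide channel, rose by 5.10 ± 0.36 (SD, n = 6). Reep6 rose by 4.57 ± 0.19, Rom1 by 4.14 ± 0.19 and Cdhr1 by 3.88 ± 0.13 (SD, n = 6 each). Drd4, a dopamine receptor gene singled out after its value was seen, did not pass, at -0.18 ± 0.63 (SD, n = 5), and had 0.023 with sighted RNA in Cy5 only and 0.019 without replicate 4. Outside the list, Nxnl2 rose by 5.30 ± 0.10, Pcare by 4.20 ± 0.35 and Vtn, the vitronectin gene, by 3.54 ± 0.24 (SD, n = 6 each). These 10 genes with the largest rise were higher in 6 of 6 replicates, with limma adjusted p between 2.36e-09 and 2.08e-07. Camera, on 15 of the 17 genes, gave the rod list an adjusted p of 1.58e-21 with a preset correlation, and an adjusted p = 0.175 with an estimated correlation.

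**Figure D1:**
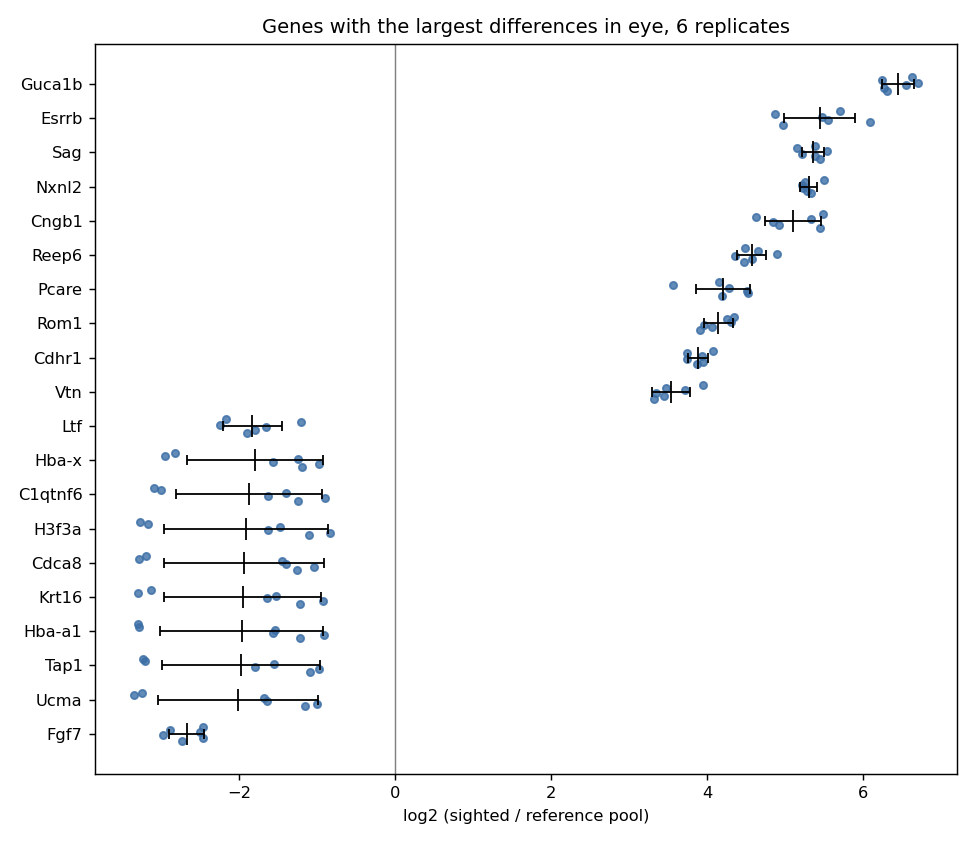
Log2 ratio of sighted over control eye RNA (axis in log2 units) for named genes, with points for the 6 replicates, a bar for the mean and whiskers for the SD. Guca1b lies at 6.45 and Fgf7 at -2.67.

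Of 4 cone genes measured, 3 rose over all genes, and 4 when adjusted over the list alone. Thrb, a thyroid hormone receptor gene, rose by 0.48 ± 0.15, Gnb3 by 0.33 ± 0.26 and Gngt2 by 0.26 ± 0.19 (SD, n = 6 each). On arrays with sighted RNA in Cy3 the last 2 turned to -0.032 and -0.039. The list did not pass camera (adjusted p = 0.0537) but passed fry (adjusted p 0.00474). Of 4 bipolar cell genes, 0 passed limma with 6009 of 15874 genes at an unadjusted p under 0.05. Pcp2 had 0.17 ± 0.16 and Scgn -0.11 ± 0.17 (SD, n = 6 each), which turned to -0.14 with sighted RNA in Cy3 only and to 0.056 with Cy5 only. Of 9 amacrine and horizontal cell genes, Calb1 rose by 0.26 ± 0.17, while Gad1 fell by 0.31 and Pax6 fell by 0.34. Calb1 turned to -0.011 with Cy3 only and Pax6 to 0.32 with Cy5 only. Of 8 ganglion cell genes, only Rbpms passed, at -0.48 ± 0.25 (SD, n = 6). Of 3 pigment epithelium genes, only Rdh5 passed, at 0.26 ± 0.15 (SD, n = 6), and it turned to -0.012 with Cy3 only.

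Of 14 lens genes measured, 11 rose in sighted eyes and 1 fell, and 12 rose when adjusted over the list alone. Crybb2, a beta crystallin gene, rose by 1.34 ± 0.42 and Crygf, a gamma crystallin gene, by 1.06 ± 0.67 (SD, n = 6 each). The list had replicate medians of 0.041 and 0.14 in replicates 1 and 5 and of 0.72 to 0.83 in the other 4, and Crygf had 0.36 and 0.23 there against 0.91 to 1.80. Crybb3 went the other way, at -0.55 ± 0.17 (SD, n = 6). Camera gave the list an adjusted p of 0.00404, and an adjusted p = 0.659 with an estimated correlation. The list did not pass fry (adjusted p = 0.0548).

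Of 13 genes of cornea and surface epithelium, 10 fell, and 10 when adjusted over the list alone. Krt14, a basal keratin gene, had -1.06 ± 0.33 and Tkt, the transketolase gene, -1.01 ± 0.26 (SD, n = 6 each). Camera gave an adjusted p of 1.15e-08, and an adjusted p = 0.218 with an estimated correlation. Of 16 skeletal muscle genes, 13 fell and 1 rose, with 14 lower when adjusted over the list alone. Actn3 had -1.18 ± 0.27 and Ckm, muscle creatine kinase, -1.13 ± 0.28 (SD, n = 6 each). The riser was Pvalb, the parvalbumin gene, at 0.45 ± 0.12 (SD, n = 6), singled out after its value was seen. The muscle list, with 15 genes in camera, had an adjusted p of 1.04e-08, and an adjusted p = 0.398 with an estimated correlation. Of 10 fat genes, 6 fell over all genes and 7 when adjusted over the list alone. Fabp4 had -0.70 ± 0.22 (SD, n = 6). The fat list had an adjusted p of 0.000131, and an adjusted p = 0.227 with an estimated correlation.

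Of 18 immune and microglia genes, 14 fell, and 14 when adjusted over the list alone. H2-K1, a histocompatibility gene, had -1.01 ± 0.18 and Lgals3 -0.85 ± 0.13 (SD, n = 6 each). Camera gave an adjusted p of 5.09e-09, and an adjusted p = 0.243 with an estimated correlation. Of 15 immediate early genes, which respond quickly to stimulation, 11 fell and 1 rose. Adjusted over the list alone, 11 fell and 2 rose. Egr1 had -1.65 ± 0.31 and Junb -1.09 ± 0.38 (SD, n = 6 each). The riser was Btg2, at 0.30 ± 0.18 (SD, n = 6), singled out after its value was seen. The list, with 14 genes in camera, had an adjusted p of 5.40e-06, and an adjusted p = 0.227 with an estimated correlation. Of 22 Mueller and astroglia genes, 6 fell and 1 rose, with 7 lower when adjusted over the list alone. Gfap, the glial filament gene, had -0.45 ± 0.20 (SD, n = 6), and Car2 had 0.35 ± 0.11 (SD, n = 6). The list had an adjusted p of 0.000843, and an adjusted p = 0.398 with an estimated correlation.

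All 3 blood genes fell, and 3 when adjusted over the list alone. A list this short had no set test. Hba-a1, an alpha globin gene, had -1.96 ± 1.05, Alas2 -1.22 ± 0.47 and Slc4a1 -0.43 ± 0.13 (SD, n = 6 each). Replicates 1 and 2 stood apart for the first 2 genes, with Hba-a1 at -3.29 and -3.27 against -1.56 to -0.91 in the others, and Alas2 at -1.68 and -1.85 against -1.22 to -0.70. Among the 10 named genes that fell most, Hba-x, another globin gene, and 6 genes that are not globins followed Hba-a1 over the replicates with a root mean square distance under 0.3. The 6 were Ucma, Tap1, Krt16, Cdca8, H3f3a and C1qtnf6, with log2 ratios between -2.01 and -1.87. Another 8 unnamed probes did the same. Fgf7, a growth factor gene, fell most, at -2.67 ± 0.23 (SD, n = 6). Ltf, the lactoferrin gene, had -1.83 ± 0.38 (SD, n = 6).

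The other lists had some called genes, to be read beside the 4259 of 15874 genes that limma called in eye. The shares of called ribosomal and matrix genes lay below that of all genes. The cardiomyocyte and ribosomal counts were the same when adjusted over the list alone. Of 21 cardiomyocyte genes, 11 fell and 4 rose, with Tcap at -0.97 and Actn2 at 0.89, and the 20 in camera had an adjusted p of 0.00141 and an adjusted p = 0.421 with an estimated correlation. Of 59 genes matched as ribosomal, 10 fell and 3 rose, with Rpl11 at -0.58 and Rpl23 at 0.43. The match also took genes that encode no ribosomal subunit, such as Rps6kb2, a kinase gene, at 0.46. The ribosomal list had an adjusted p of 4.96e-05, and an adjusted p = 0.659 with an estimated correlation. Of 26 extracellular matrix genes, 4 fell, and 2 when adjusted over the list alone, with Fn1 at -0.52. The matrix list, with 25 genes in camera, had an adjusted p of 0.0241, and an adjusted p = 0.659 with an estimated correlation. Without replicate 1 the matrix list had an adjusted p of 0.0983, and without replicate 2 of 0.102.

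Of 15 synapse genes, 4 rose, among them Syp by 0.64 ± 0.20 (SD, n = 6), and 0 fell. Of 16 clock genes, 5 rose and 4 fell, with Rora at 0.71, Bhlhe41 at 0.59, Per2 at -0.64 and Hlf at -0.61. Of 16 fatty acid oxidation genes, 4 rose and 6 fell, with Ppara at 0.56 and Acaa2 at -0.65. Of 13 heat shock genes, Hsp90aa1 and Cryab rose by 0.56 and 0.29, while Hspb8 and Bag3 had -0.91 and -0.69. The heat shock list had a median of 0.07 and a mean of -0.03. Of 28 oxidative phosphorylation genes, Cox8b, Cox5a and Cox7a1 fell, at -0.51, -0.71 and -0.64. Of 8 hormone genes, Pomc and Sst rose by 0.43 and 0.36, and Npy had -0.71. Of 10 myelin genes, Mbp, Trf and Cldn11 fell, at -0.35, -0.28 and -0.24. Of 6 choroid plexus genes, Igf2 rose by 0.39 and Folr1 had -0.57. Of 6 atrial genes, Myl4 and Ccn2 fell, at -0.48 and -0.30. Of 14 cortex and striatum genes, 3 rose and 4 fell, among them Tcf7l2 at -0.36 and Prkcd at -0.38. Rgs9 was in that list and the rod list, at 1.69 ± 0.09 (SD, n = 6), but its probes differed, at 3.34 and 0.05. On arrays of a single dye orientation Pomc turned to -0.090, Trf to 0.0021, Ccn2 to 0.058 and Tcf7l2 to 0.011. None of these 10 lists passed camera. The shares of called synapse, heat shock, myelin, choroid plexus and atrial genes lay near that of all genes. The share of oxidative phosphorylation genes lay below it. The shares of clock, fatty acid oxidation, hormone, and cortex and striatum genes lay above it. Fry passed the synapse list (adjusted p 0.0303) and the cortex and striatum list (adjusted p 0.0247).

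**Figure D2:**
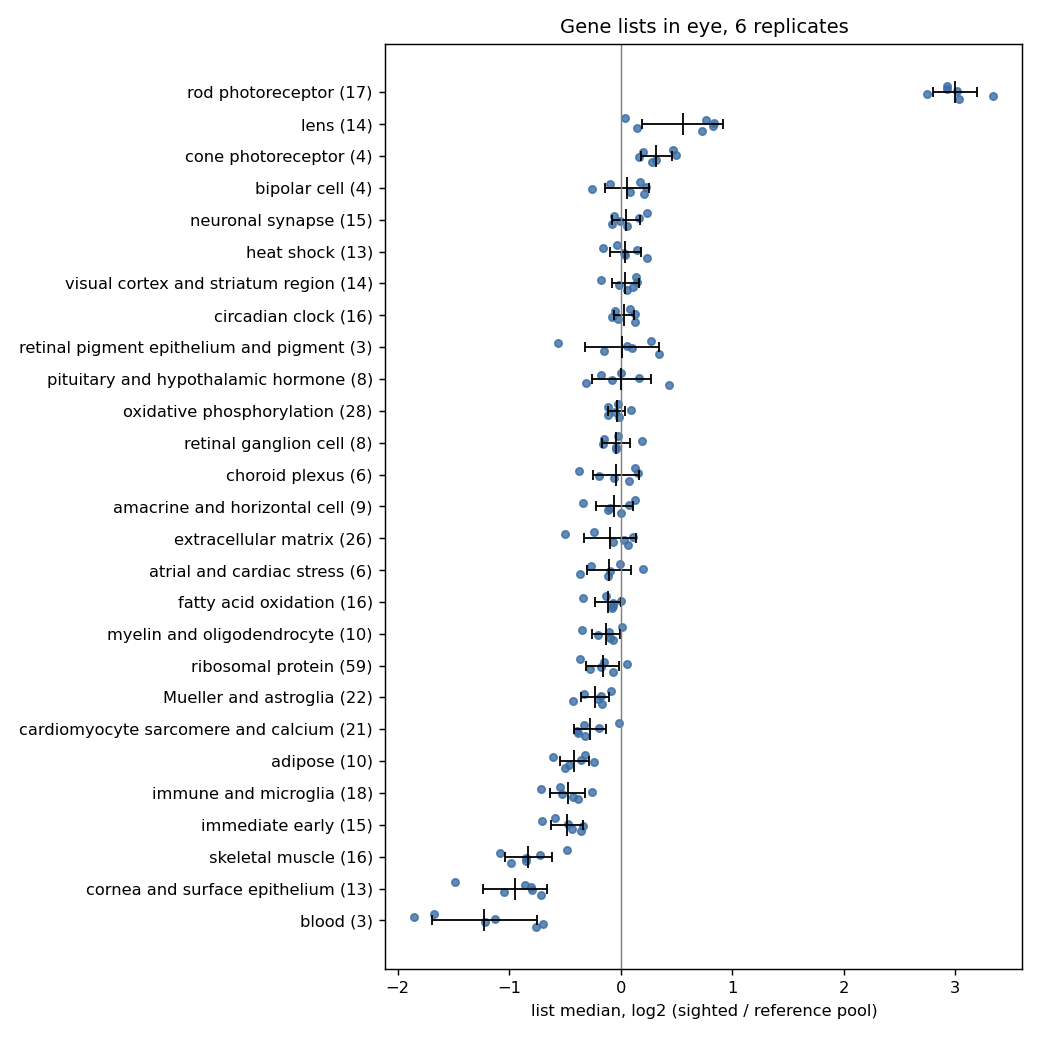
Median log2 ratio of sighted over control eye RNA (axis in log2 units) for the gene lists, with points for the 6 replicates, a bar for the mean and whiskers for the SD. The rod list has a mean of replicate medians of 3.00 and the cornea list one of -0.95.

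The split of the eye calls depended on the dye. Arrays with sighted RNA in Cy5 called 6072 genes higher and 508 lower, and arrays with sighted RNA in Cy3 called 553 higher and 3394 lower. Both orientations enter each replicate equally in the counts above. Centring every array on its median called 2537 higher and 2410 lower. Among the named genes called in eye, 10 values changed sign on arrays of a single orientation, among them those of Pax6, Calb1 and Rdh5.

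The second comparison asked the same of the brain. Gh, the growth hormone gene, had -1.67 ± 0.34 (SD, n = 6), 3.18-fold lower, with a limma adjusted p of 0.0136, and was lower in 6 of 6 replicates. It was the only gene of 16112 past the threshold, with 657 at an unadjusted p under 0.05. Prl, the prolactin gene, had -2.69 ± 0.81 (SD, n = 6), 6.44-fold lower in 6 of 6 replicates, and did not pass (adjusted p = 0.0725). Prl did pass with every array on its own (limma adjusted p 0.000239), with the pair as a random block (0.000245) and with scaled arrays (0.0383). The first of these may count colour flips of the same animal as separate samples. The random block models only the pairs read from the array numbers. Prl also passed where a gene needed every replicate (0.0455), without the genes of most spread (0.0145) and without replicate 3 (0.0336). With sighted RNA in Cy5 only (0.0247) or Cy3 only (0.0151) Prl passed too, but there the dye effect does not cancel, and 736 and 1327 genes were called. Its unadjusted limma p was larger there, at 2.84e-05 and 2.10e-05 against 8.99e-06 with both orientations, so these passes add no support. Over all settings the adjusted p of Prl ranged up to 0.471. Gh lost its call without replicate 1, 2, 3, 4 or 6, with adjusted p of 0.0774, 0.125, 0.0530, 0.122 and 0.120, while its log2 ratio stayed between -1.72 and -1.63. It kept its call without replicate 5, at 0.00623, and lost it with ceiling values kept, at 0.0537.

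Of 8 hormone genes, 1 fell over all genes. Adjusted over the list alone, 2 fell and 1 rose. The replicate medians of the list had a mean of -0.18 ± 0.14 (SD, n = 6). Camera, on 6 of the genes, gave an adjusted p of 0.00777, and an adjusted p = 0.416 with an estimated correlation. Npy, the neuropeptide Y gene, had 0.62 ± 0.40 (SD, n = 6) and did not pass. The heat shock list, with 0 of 13 genes called and 1 lower when adjusted over the list alone, had a mean of replicate medians of -0.075 ± 0.053 (SD, n = 6). Hspa5 had -0.29 ± 0.14 and Hsph1 -0.15 ± 0.09 (SD, n = 6 each). Its camera adjusted p, on 12 genes, was 0.00777, with an adjusted p = 0.470 with an estimated correlation and 0.299 without replicate 1. Rod genes had a mean of replicate medians of 0.066 ± 0.032 (SD, n = 6) in brain. The other brain lists with a set test had camera adjusted p between 0.253 and 0.971. Of these, the rod and matrix lists passed fry (adjusted p 0.0402 each). Among named genes that did not pass, those with the smallest p in each direction were, besides Prl and Npy, Srp54a at -0.53, Mgat4b at -0.58, Ifi205 at -0.51, 4833420G17Rik at 0.61, Atoh8 at 0.39, Pgm2l1 at 0.31 and Gatb at 0.44, with adjusted p between 0.134 and 0.959. Ifi205 turned to 0.083 with sighted RNA in Cy5 only.

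**Figure D3:**
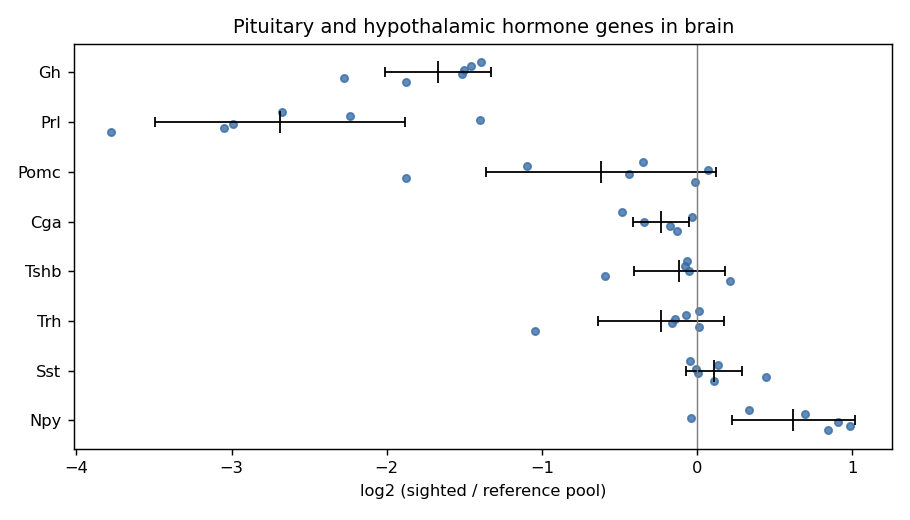
Log2 ratio of sighted over control brain RNA (axis in log2 units) for pituitary and hypothalamic hormone genes, with points for the 6 replicates, a bar for the mean and whiskers for the SD. Gh lies at -1.67 and Prl at -2.69.

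The third comparison asked the same of the heart. Limma called 0 of 12755 genes, with 1042 at an unadjusted p under 0.05. Only 7099 genes had a value in all 4 replicates, and the others rested on 3. The oxidative phosphorylation, fatty acid oxidation and matrix lists had replicate medians with a mean of 0.28 ± 0.077, 0.29 ± 0.088 and 0.21 ± 0.12 (SD, n = 4 each). They passed camera, with an adjusted p = 0.302, 0.366 and 0.302 with an estimated correlation. Of 27 oxidative phosphorylation genes, Sdha had 0.63 ± 0.26 and Uqcrc2 0.48 ± 0.05 (SD, n = 4 each). Of 15 fatty acid oxidation genes, Hadh had 0.49 and Hadha 0.40. In simulated data of the same spread, with 200 genes changed, the heart test recovered 22.4% of genes changed by a log2 of 1 and 63.6% of those changed by 2. These shares can be too high where fewer genes change.

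Camera called 6 heart lists, each with 0 called genes. Oxidative phosphorylation, with 25 genes in camera, had an adjusted p of 1.65e-08, and an adjusted p = 0.302 with an estimated correlation. Ribosomal genes, 48 of 57 in camera, had a mean of replicate medians of 0.17 ± 0.036 (SD, n = 4) with an adjusted p of 2.23e-06, and an adjusted p = 0.302 with an estimated correlation. Rpl28 had 0.54, with a replicate at 1.01. Rpl32 had 0.53, and turned to -0.51 with sighted RNA in Cy3 only and to -0.16 where 1 array was enough for a replicate. Matrix genes, 21 of 24 in camera, had an adjusted p of 0.000271, and an adjusted p = 0.302 with an estimated correlation. Col1a1 had 0.66 and Col6a1 0.54. Fatty acid oxidation had an adjusted p of 0.000271, and an adjusted p = 0.366 with an estimated correlation. Cardiomyocyte genes, 20 of 21 in camera, with Pln at 0.53 and Tcap at 0.38, had an adjusted p of 0.00398, and an adjusted p = 0.685 with an estimated correlation. Pln turned to -0.067 with Cy5 only. Without replicate 3 the list's adjusted p was 0.0681. Mueller and astroglia genes, 11 of 19 in camera, with Apoe at 0.42, had an adjusted p of 0.0304, and an adjusted p = 0.333 with an estimated correlation. Aqp4, at -0.65 ± 0.33 (SD, n = 3), was not among the 11. Without replicate 1, 2 or 4 it was 0.122, 0.0767 or 0.139.

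The 6744 genes measured on all 32 arrays had a heart median of 0.02 and the other 6011 genes one of -0.06. Among named genes that did not pass, those with the smallest p in each direction were Fhl1 at 0.92, 2310002L09Rik at 0.96, Psmb3 at 0.91, Gfm1 at 0.67, Rab2a at 0.71, Higd1b at -1.43, Far1 at -0.96, Mycbp2 at -0.82, Crabp1 at -0.99 and Gdf9 at -1.10. All had an adjusted p of 0.568. The direction of 5 depended on the handling: with ceiling values kept Fhl1 had -0.55 and Mycbp2 0.060, with Cy3 only Psmb3 had -0.19, and with Cy5 only Far1 had 0.10 and Crabp1 0.34. The other heart lists with a set test had camera adjusted p between 0.0678 and 0.948.

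The fourth comparison tested whether the ratio differed between organs. The 5 named genes with the smallest p were Guca1b, Sag and Cplx4 of the rod list and Nxnl2 and Pcare outside it, all with a higher ratio in eye than in both other organs. Guca1b differed by 6.43 from brain and by 6.51 from heart, and Sag by 5.26 and 5.78. Nxnl2 differed by 5.34 and 5.43, Pcare by 4.13 and 4.42, and Cplx4, a complexin gene, by 3.21 and 3.87. With 1 spread shared by the organs, limma called 1564 of 12492 genes between eye and brain and 2844 between eye and heart. With each organ's own spread, chosen after seeing the data, it called 2670 and 601, and these 5 genes kept adjusted p between 5.03e-18 and 0.000122.

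Between brain and heart no gene difference held under both spreads. The shared spread called 357 genes and each organ's own spread called 0, with 1131 at an unadjusted p under 0.05 (limma). Simulated data without any change gave 235 calls with the shared spread and 4 with each organ's own. The median SD between replicates was 0.181 in brain and 0.340 in heart. Without any change between eye and heart the same simulation gave 226 and 4. The simulation took sample SDs as true, which can widen the differences in spread between organs. The shared-spread counts can therefore be too high. With 200 genes changed by a log2 of 1 between eye and heart, each organ's own spread recovered 97 and the shared spread 164. Gh differed by -1.89, H2aj by -0.84, Uqcrc2 by -0.53, Aar2 by 0.56 and Asap1 by 0.79, each with an adjusted p of 0.549 under each organ's own spread. With the replicate number as a block the shared spread called 2, and with a replicate left out between 63 and 957.

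Limma called 0 genes in more than 1 organ, with 657 and 1042 genes at an unadjusted p under 0.05 in brain and heart, where independent calls would give at most 0.109. With every array on its own, 3 were called in both eye and brain, namely 4833420G17Rik and a pair of unnamed probes. That setting may count colour flips of the same animal as separate samples.

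The last comparison asked whether genes next to Pde6b on chromosome 5 were called more often in the eye. Of 75 tested genes among the 200 on each side, 20 were called (26.7%), against 2570 of 8483 elsewhere (30.3%). The odds ratio was 0.837 with a 95% interval from 0.474 to 1.42 (Fisher's exact test, two-sided, p = 0.531).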

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

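The tests of blood, pituitary tissue, dye bias, dilution, array constants and tissue from around the eye, the counts over regrouped replicates, the left-out replicates for the pituitary genes, the fits with each organ's own spread and the simulation of unequal spread were chosen only after the result was seen.

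Of 217 groups of replicates or arrays tested for a value far from the others, 11 had one, and chance alone gives about 1 in 20. In eye these were Cldn11 with a replicate at -0.57, Syt1 at 0.62, Cox5a at -1.69, Pomc at 0.19 and Rbpms at -0.97. In brain, 4833420G17Rik had a replicate at 0.11, while the others lay between 0.63 and 0.90. The brain hormone list had a replicate median of -0.44 and the brain skeletal muscle list one of 0.0505. In heart, Rpl28 had a replicate at 1.01, and the rod list had a replicate median of 0.66 against -0.24 to -0.12 in the others. A heart array, number 7, had 61.58% of its values missing, against 5.96 to 11.99% on the others. It belongs to replicate 4, which also held the rod median of 0.66.

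With a shared spread limma called a different ratio between eye and brain for 1564 genes, between eye and heart for 2844 and between brain and heart for 357. With each organ's own spread it called 2670, 601 and 0, the last with 1131 at an unadjusted p under 0.05. In simulated data without a change the shared spread gave 226 calls between eye and heart and 235 between brain and heart. These counts can be too high, since the simulation took sample SDs as true. The named differences between eye and brain were Guca1b 6.43, Sag 5.26, Nxnl2 5.34, Cplx4 3.21 and Pcare 4.13. Those between eye and heart were Guca1b 6.51, Sag 5.78, Cplx4 3.87, Nxnl2 5.43 and Pcare 4.42. Those between brain and heart were Gh -1.89, Aar2 0.56, Asap1 0.79, H2aj -0.84 and Uqcrc2 -0.53, and none of these 5 passed with each organ's own spread.

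Other groupings of the replicates were counted. A chance deviation of an organ's single control pool shifts every replicate alike, so these counts cannot exclude it. For the eye, 1 of 32 sign patterns, the real one, gave as many as 4259 genes, and the highest other gave 1. The dye labels set the signs, and the rod genes already had 1 direction in all eye replicates. Other patterns were therefore bound to call fewer genes, and this count shows only that the replicates share a direction. For the brain, 1 of 32 gave as many as 1 gene and the highest other gave 0, which rests on the single gene Gh, whose call is lost without replicate 1, 2, 3, 4 or 6 (limma adjusted p 0.0774, 0.125, 0.0530, 0.122 and 0.120) at a log2 ratio that stayed between -1.72 and -1.63. For the heart the 8 patterns are too few, with 0 genes in the real one and 0 as the highest other, and 8 as large. Between eye and brain 1 of 100 splits, the real one, was as large, with 0 as the highest other. Between eye and heart it was again only the real one of 100, with 44 as the highest other. Mixing eye replicates with those of another organ puts the rod difference into the spread within groups. Other splits were therefore bound to call fewer genes, and these counts are no separate test. Between brain and heart only the real one of 100 was as large, with 18 as the highest other. Regrouping does not guard against unequal spread, as the calls in simulated data show.

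In eye, 6 named genes other than globin genes and 8 unnamed probes followed Hba-a1. If globin sequence bound these probes, they would follow Hba-a1 in brain too, and their median percentile of closeness there was 99.8 among 14961 genes. Globin sequence on probes that carry other names would give this, but so would transcripts that vary with the blood content of a sample. The values cannot tell these apart, and no probe sequence was checked. Krt16, Tap1, Ucma, Cdca8, H3f3a and C1qtnf6 may therefore not report their own genes. The red cell genes Alas2 and Slc4a1 had a mean of -0.82 ± 0.26 (SD, n = 6), as more blood in the eyes of the control pool would give, but 1 pool cannot give the gap of Hba-a1 between replicates 1 and 2 (-3.29 and -3.27) and the others (-1.56 to -0.91). More blood in the pool cannot be told apart from a difference between the mouse lines, because 1 pool serves all arrays.

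In brain, Gh had -1.67 and passed, and Prl had -2.69 and did not (limma adjusted p 0.0136 and 0.0725). Dye bias was excluded as the cause of these values, since the mean nearest to 0 in either orientation was -1.64 (Gh, sighted RNA in Cy3). The other pituitary genes Pomc, Cga and Tshb had a mean of -0.39 ± 0.37 (SD, n = 6), below 0 in 5 of 6 replicates. Without replicate 1, 2 or 4 this mean lay within its SD (-0.41 ± 0.41, -0.39 ± 0.41 and -0.36 ± 0.41, n = 5 each), and Tshb alone turned to 0.0051 without replicate 4. Pituitary tissue in the control pool therefore stays open, and it cannot be told apart from a difference between the lines, because 1 pool serves all arrays.

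In eye, 10 of 13 cornea, 13 of 16 muscle, 6 of 10 fat and 14 of 18 immune genes fell and 1 muscle gene rose. The camera calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.218 to 0.398), as was that of the rod list (adjusted p = 0.175). That setting passed no list in any organ, so the loss does not single these lists out. The cornea list lay below the inner retina lists by more than the spread (-0.94 ± 0.35, SD, n = 6). This argues against dilution by photoreceptor RNA as the whole cause only if inner retina RNA was alike in both lines, which was not measured. Pcp2, Scgn, Calb1 and Pax6 of the inner retina lists also changed sign on arrays of a single dye orientation. Dilution therefore cannot be excluded. All 4 lists lay below the median of all genes by more than the spread, the nearest to 0 being fat at -0.45 ± 0.12 (SD, n = 6). A constant added to every gene of an array would not give this. The lists were picked after camera had placed them below the other genes of these replicates, so this is no separate test. The muscle, fat and cornea lists lay below 0 in all 6 replicates, 3 of 3 lists, as more tissue from around the eye in the pool would give. This cannot be told apart from a difference between the lines, because 1 pool serves all arrays.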

How the results depend on the processing

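Fits with each organ's own spread, with ceiling values kept, without chosen replicates together, without genes that follow Hba-a1, the list tests and the pituitary and red cell means with a replicate left out and the check of replicate numbers between organs were chosen after seeing the data. The heart lists with every array on its own were run without array 7, and the planned version with it was not run. No probe named Pde6b exists here, so the settings meant for it were not run. No signal over background was used here, so the limit it sets on single spots stays unknown.

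In eye, the count of 4259 genes lay between 2994 and 5061 in all settings but arrays with sighted RNA in Cy5, which gave 6580. Single probes gave 5160 probes of 4733 genes. It was 2994 without replicates 1 and 2, 4247 without genes that follow Hba-a1 and between 3301 and 4208 with 1 replicate left out. Of 105 named genes called in eye, 57 kept sign and call in every setting and 84 in every setting but a single dye.

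In brain, the count of 1 became 6 with every array on its own, 6 with the pair as a random block, 2 with scaled arrays, 2 where a gene needed every replicate and 3 without the genes of most spread, with Prl among them in each. It was 736 with sighted RNA in Cy5 only and 1327 with Cy3 only, where the dye effect does not cancel by construction. With ceiling values kept limma called 0, with 611 genes at an unadjusted p under 0.05 and Gh at an adjusted p of 0.0537. Over all settings the adjusted p of Gh lay between 9.98e-05 and 0.125. With a replicate left out the count lay between 0 and 1, and limma called 0 without replicate 1, 2, 4 or 6, with 608 to 719 genes at an unadjusted p under 0.05. Without replicate 3 the 1 gene was Prl, with a limma adjusted p of 0.0336 in a range from 0.0336 to 0.471 over left-out replicates. In heart it was 0 in every setting, with 577 to 2454 genes at an unadjusted p under 0.05.

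Between organs, each organ's own spread gave 2670, 601 and 0 genes for eye and brain, eye and heart, and brain and heart, the last with 1131 at an unadjusted p under 0.05 (limma). The replicate block gave 1272, 2277 and 2. The labels do not say that a number pairs samples between organs, and across genes the deviations of replicates with the same number correlated by -0.0614 to 0.0264 between organs. Within an organ, arrays correlated best with their own number in 12 of 12 eye, 4 of 12 brain and 1 of 8 heart arrays. With a replicate left out the counts lay between 1307 and 1524, 2365 and 3436, and 63 and 957. For brain and heart they were 100, 167, 63, 103, 180 and 107 without brain replicates 1 to 6, and 957, 651 and 622 without heart replicates 1, 2 and 4.

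With an estimated correlation 0 lists passed camera in eye, 0 in brain and 0 in heart, against 11, 2 and 6, with 5, 2 and 2 at an unadjusted p under 0.05. Calls were also lost where the estimate lay below the preset 0.01, as for the brain hormone list (-0.134) and the heart matrix list (-0.0247). A lost call is therefore not by itself a sign of correlation between genes. With a replicate left out 10 to 12, 1 to 3 and 5 to 6 passed camera at the preset correlation, with 1 in brain without replicate 1. Fry did not pass the eye ribosomal, lens and matrix lists (adjusted p = 0.137, 0.0548 and 0.253), which camera passed. Nor did it pass the brain heat shock list (adjusted p = 0.0855) or the heart cardiomyocyte list (adjusted p = 0.122). Fry passed the eye cone, synapse, and cortex and striatum lists and the brain rod and matrix lists, which camera did not. With every array on its own 3 genes were called in more than 1 organ. The odds ratio near Pde6b lay between 0.619 and 0.872.

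Values changed sign with sighted RNA in Cy5 only for Pax6 (0.32), Ccn2 (0.058), Timp2 (0.036), Trf (0.0021), Tcf7l2 (0.011), Drd4 (0.023) and Scgn (0.056) in eye, Ifi205 (0.083) in brain, and Far1 (0.10), Crabp1 (0.34) and Pln (-0.067) in heart. With Cy3 only they did for Calb1 (-0.011), Gnb3 (-0.032), Gngt2 (-0.039), Pomc (-0.090), Rdh5 (-0.012) and Pcp2 (-0.14) in eye, and Psmb3 (-0.19) and Rpl32 (-0.51) in heart. With 1 array enough for a replicate, Rpl32 was -0.16 in heart. With ceiling values kept, Fhl1 was -0.55 and Mycbp2 0.060 in heart. Drd4 was 0.019 in eye without replicate 4, and Tshb 0.0051 in brain without replicate 4. Where no construction is named, the cause was not tested.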

Other observations

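The genes in this part were singled out after their values were seen.

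The transcript 4833420G17Rik rose in eye and had values above 0 in brain and heart, where it did not pass. In eye it had 1.88 ± 0.18 (SD, n = 6), higher in 6 of 6 replicates with a limma adjusted p of 1.42e-06. In brain it had 0.61 ± 0.26 (SD, n = 6), higher in 6 of 6 replicates, and did not pass (adjusted p = 0.542). In heart it had 0.73 ± 1.17 (SD, n = 3), higher in 3 of 3 replicates, and did not pass (adjusted p = 0.600). With every array on its own, which may count colour flips of the same animal as separate samples, it was called in eye and brain. So were 2 unnamed probes. Of these, 1 had 1.09 in eye and 0.42 in brain, and the other had -1.05 and -0.57.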
